A study of Mus musculus with 12 samples.

How the data were processed

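Livers of C57BL/6 mice were sequenced in 4 groups of 3 samples, and the groups were taken from the samples' labels on diet and treatment. Total RNA was isolated with a column kit, and stranded libraries of polyadenylated RNA were sequenced in read pairs, per the labels' protocols. The labels' protocols and the design text of the series name different Illumina HiSeq instruments, so the instrument is left open. Reads were aligned with STAR 2.7.3a to the mouse build mm10, per the submitters' processing notes. The tool that counted reads per gene, its strand setting and its annotation release are not given in the sources used here.

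The authors deposited 1 table of counts per gene, with 55471 gene IDs and 12 columns of whole-number counts, and 0 columns lay outside the samples. Each column was tied to its sample by the title. In 1 case the title gave replicate 5 where the library name gave 8, and the title was followed. Gene symbols, positions (mm10, the same assembly as GRCm38), types, transcript lengths and GC contents were taken from GENCODE release vM21, which matched 55144 IDs. The other 327 IDs held 0.0105% of the counts and were kept under their IDs, and 11 of them were tested. The unstated strand setting matters for overlapping and antisense genes, whose counts cannot be separated here. Members of the Mup, Serpina1, Cyp2a, Cyp2c, Hsd3b, Apol9 and H2 families share near-identical sequence, so their counts depend on how shared reads were treated. Their values are uncertain wherever they are given below, also where this is not repeated. The same may hold for other genes with close relatives, such as Cyp4a31 and Selenbp2.

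All values given as CPM (counts scaled to library size), log2 fold changes and p-values were computed here from the deposited counts. Depth ran from 30213048 to 41852606 counts per library. With edgeR 4.0.16 in R 4.3.3, genes were filtered with filterByExpr by group, which left 13866 of the 22984 genes with any count, libraries were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit with 1 coefficient per group. Each comparison was a two-sided quasi-likelihood F test of a contrast, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a single gene below comes from this test, and the error of a log2 fold change is its standard error (SE), the absolute log2 fold change divided by the square root of F. Errors of CPM are standard deviations over the 3 samples of a group. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

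Gene lists were written down before the data were examined, together with the groups, the tests, the other settings and the rule for naming genes. Each list with at least 5 tested members was tested with camera (limma 3.58.1, voom log2 CPM, preset correlation 0.01), with camera at a correlation estimated per list, and with fry, and adjusted over the lists. No camera call held with an estimated correlation. Counts of members that rose and fell are given over all genes tested and, in brackets, adjusted over the list alone. A list fixed for ribosomal protein genes by symbol also took Rps6k kinase genes, which are not ribosomal proteins. Genes were named by rule: per comparison the 6 largest rises and the 6 largest falls among genes that passed, with a mean of at least 1 CPM in the higher group and no overlap of samples, without predicted genes and pseudogenes, then up to 2 members of a list per direction with the smallest adjusted p, and 18 genes fixed in advance whatever their result. Of these 18, Tnf did not pass the filter. Some genes that the rule took are not reported here.

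A fold against a group with no counts was computed against a floor of 3 counts over that group, and with 1 to 3 counts the ratio is given with its 95% counting interval. These cover counting error only. For comparisons that share libraries, the overlap of independent lists and 20 simulations of unchanged groups were computed. Other settings fixed at that point were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter at a mean of 1 CPM, fits of only the groups compared, a replicate block, stricter thresholds and leaving out each library. A block by the numbers in the library names, removal of a trend with GC content and transcript length within each library, and runs without the library of each dose with the strongest such trend were added after the data were seen.

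The fits were tested on simulated counts with 200 changed genes before use. Among changed genes with a 2-fold change, the test recovered 56.7% in the comparison of diets, 68.4% at 0.1x, 68.2% at 1x and 70.0% between the doses. At a 4-fold change it recovered 90.9%, 85.2%, 90.5% and 93.4%, and at 1.5-fold 18.0%, 24.6%, 14.0% and 23.4%. Replicate libraries of a group differed by more than sampling noise in every pair (lowest chi-square per degree of freedom 16.0), so no 2 columns were repeat counts of 1 library. That test does not separate different animals from separately prepared libraries of 1 animal, and the samples were counted as separate on the labels alone.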

Results

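The series asked how DNMT1, the enzyme that copies DNA methylation to new DNA strands, bears on MASLD (metabolic dysfunction-associated steatotic liver disease, fat in the liver with metabolic disease). Gene expression was measured by RNA-seq in livers of mice on a standard diet (SD), on a diet that gives MASLD, and on the MASLD diet with Aza-TdC at relative doses of 0.1x or 1x. Aza-TdC is a nucleoside analogue that depletes DNMT1 after its incorporation into DNA. The absolute dose and the diet's composition are not given in the labels. Each group had 3 samples, and totals ran from 30213048 counts (0.1x sample 3) to 41852606 counts (1x sample 2).

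Alb, the serum albumin gene, took 10.4 ± 0.732% of counts in SD and 7.60 ± 0.643% in MASLD (mean ± SD, n = 3). The 50 most abundant genes took 35.5 to 42.6% of counts per library. On the first principal component (36.5% of variance) SD lay at −55.3 ± 4.58, MASLD at 34.0 ± 8.49, 0.1x at 12.7 ± 3.65 and 1x at 8.61 ± 4.11. The second (15.6%) parted 0.1x (−33.4 ± 13.98) from 1x (18.5 ± 11.1), and also from MASLD (12.1 ± 6.44), which overlapped 1x. SD lay at 2.82 ± 11.4. The extremes were 0.1x sample 3 (−48.2) and 1x sample 2 (29.9), the libraries with the strongest trend described next, so this component may not be one of dose. Libraries also differed in a trend of counts with GC content and transcript length. It explained 36.1% of the variance of a library's deviation from the mean in 0.1x sample 3, 27.9% in 1x sample 2 and 20.6% in MASLD sample 5. Pairs of replicates had Spearman correlations of 0.981 to 0.993 across genes.

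**Figure D1:**
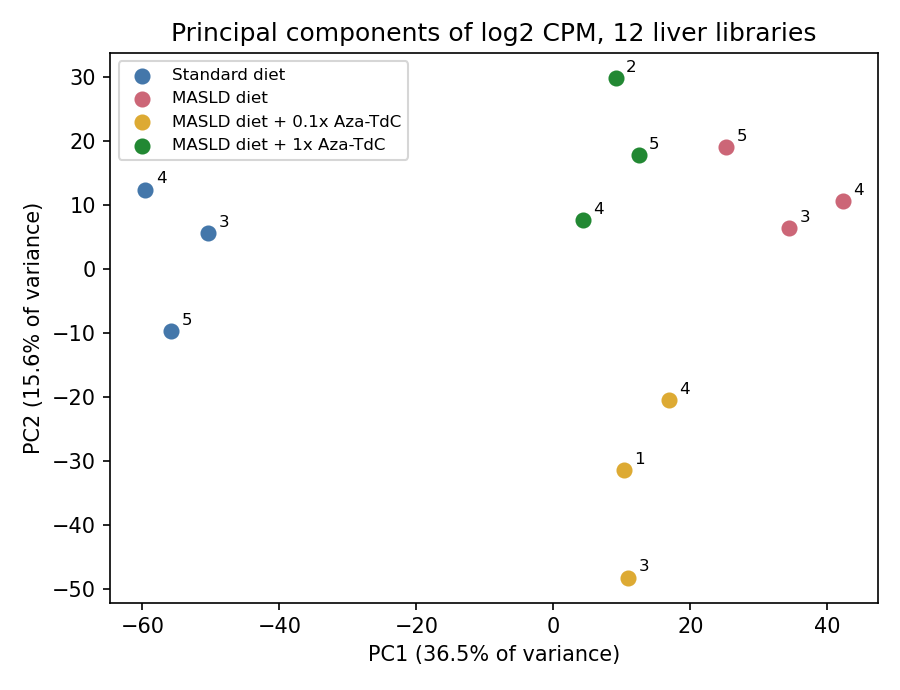
Principal components of log2 CPM over the tested genes, 1 point per library, coloured by group, with the variance of each component in percent on its axis. SD libraries lie apart from the other groups on the first component, and the 0.1x libraries lie below the 1x libraries on the second.

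Dnmt1 (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888) stood at 6.43 ± 0.769 CPM in SD, 9.12 ± 0.547 in MASLD, 6.06 ± 0.702 at 0.1x and 8.22 ± 1.83 at 1x. It rose on the MASLD diet (log2 fold change 0.50 ± 0.17, adjusted p = 0.0335) and fell at 0.1x against MASLD (−0.59 ± 0.17, adjusted p = 0.0336). At 1x it differed from MASLD by −0.15 ± 0.16 (adjusted p = 0.730), and between the doses by 0.44 ± 0.17 (adjusted p = 0.0918). With the GC and length trend removed neither call held, at 0.30 for the diet (adjusted p = 0.149) and −0.21 at 0.1x (adjusted p = 0.462). In the comparison of diets Dnmt1 did not pass without MASLD sample 3, 4 or 5 or SD sample 3 or 5 (adjusted p from 0.0664 to 0.115), and at 0.1x Dnmt1 did not pass without 0.1x sample 1 or 3 or MASLD sample 3, 4 or 5 (adjusted p from 0.0666 to 0.109). Aza-TdC acts on the DNMT1 protein, which was not measured. The de novo methyltransferases Dnmt3a and Dnmt3b and the DNMT1 partner Uhrf1 passed in none of these 4 comparisons (Uhrf1 on the diet 1.01 ± 0.61, Dnmt3a at 0.1x −0.41 ± 0.18). With the trend removed Dnmt3a turned to 0.12 at 0.1x (adjusted p = 0.777). On the diet 1 of 21 genes of DNA methylation and demethylation rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.759). At 0.1x 1 of 21 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.3001), and at 1x 0 of 21 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.809). Mbd1, which reads methylated DNA, fell by 0.68 ± 0.15 at 0.1x (adjusted p = 0.0145), and Mbd1 did not pass without MASLD sample 3 or 5 (adjusted p from 0.0509 to 0.0644).

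The MASLD diet raised genes of fat storage and uptake. Cidec (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), which fuses lipid droplets, went from 2.96 ± 1.35 to 235 ± 13.96 CPM, a log2 fold change of 6.32 ± 0.33 (adjusted p = 3.6e-08). Cidea, its relative, rose by 8.03 ± 1.06, and Cd36, a fatty acid transporter, by 2.85 ± 0.25. Aqp7, a glycerol channel, had no count in SD and was at least 106-fold higher on the MASLD diet. In all 15 of 25 lipid droplet and uptake genes rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 7.4e-08, adjusted p = 0.317 with an estimated correlation). Among lipid synthesis genes 14 of 26 members rose and 5 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.00136, adjusted p = 0.398 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose from 7893 ± 2033 to 36489 ± 3669.9 CPM (2.21 ± 0.20) and Mogat1, an acyltransferase, by 3.11 ± 0.24, whereas Acss2 (−1.14 ± 0.25) and Dgat2 (−0.61 ± 0.11) fell. Fasn, the fatty acid synthase, did not pass at 0.62 ± 0.34 (adjusted p = 0.190).

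Fatty acid oxidation genes rose as well. For PPARA, the fatty acid-sensing receptor, 21 of 34 targets rose and 0 fell (22 and 2 adjusted over the list alone; camera adjusted p = 1.1e-09, adjusted p = 0.331 with an estimated correlation). Ehhadh, a peroxisomal oxidation enzyme, went from 306 ± 18.2 to 1183 ± 9.09 CPM (1.95 ± 0.11), Cyp4a31 rose by 3.45 ± 0.20, and the hormone gene Fgf21 by 3.56 ± 0.31. Klb, the co-receptor of FGF21, did not pass (−0.33 ± 0.15, adjusted p = 0.101), and with the GC and length trend removed it did (−0.39, adjusted p = 0.0464). Other genes with no count in SD were Tinag (at least 38.9-fold higher), Ucp3 and Spire2 (at least 34.4-fold higher each). Apoa4, an apolipoprotein, rose by 5.11 ± 0.23 to 6849 ± 1024 CPM. Cyp2a4, whose reads may be shared with Cyp2a5, rose by 6.61 ± 0.68. Cholesterol synthesis went the other way, where 1 of 26 genes rose and 15 fell (2 and 18 adjusted over the list alone; camera adjusted p = 7.7e-08, adjusted p = 0.398 with an estimated correlation). The sterol enzymes Tm7sf2 (−1.84 ± 0.13) and Ebp (−1.21 ± 0.14) fell.

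Matrix and macrophage genes rose on the MASLD diet, where 28 of 39 fibrosis and matrix genes rose and 0 fell (31 and 1 adjusted over the list alone; camera adjusted p = 6.2e-09, adjusted p = 0.398 with an estimated correlation). Mmp12, a macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), went from 0.0914 ± 0.0742 to 5.44 ± 2.81 CPM (5.80 ± 0.68), Postn rose by 1.32 ± 0.13, Timp1 by 3.43 ± 0.72 and the collagen gene Col1a1 by 2.40 ± 0.76 (adjusted p = 0.0275). Acta2, the smooth muscle actin of activated stellate cells, did not pass (0.32 ± 0.76). For lipid-associated macrophages 14 of 19 markers rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 7.2e-06, adjusted p = 0.398 with an estimated correlation). They included Gpnmb (5.59 ± 1.04), Trem2 (2.79 ± 0.57), Cd63 (2.79 ± 0.32) and Anxa5 (ENSMUSG00000027712, chromosome 3, 36448923 to 36475894), which rose by 1.86 ± 0.18. For monocytes 12 of 18 markers rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 3.5e-05, adjusted p = 0.398 with an estimated correlation), among them S100a11 (3.12 ± 0.31). Ccl2, which draws monocytes, rose by 2.49 ± 0.67. Col1a1 did not pass without MASLD sample 4 or SD sample 4 or 5 (adjusted p from 0.0682 to 0.135), and Ccl2 did not pass without MASLD sample 4 (adjusted p = 0.0681).

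Markers of other cell types moved in the same livers. In Kupffer cells, the resident macrophages, 9 of 18 markers rose and 0 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.00159, adjusted p = 0.442 with an estimated correlation). Of 18 sinusoidal endothelial markers 11 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.7e-05, adjusted p = 0.398 with an estimated correlation), and 11 of 21 stellate cell markers rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.398 with an estimated correlation). Of 16 cholangiocyte markers 10 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.00953, adjusted p = 0.490 with an estimated correlation). Their mean log2 CPM was 3.22 in MASLD sample 4 against 2.13 in each of the other 2, and without that sample the cholangiocyte list still passed on the diet (camera adjusted p = 0.0239). Of 32 cell cycle genes 18 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 5.5e-05, adjusted p = 0.398 with an estimated correlation), with Ccnd1, cyclin D1, up by 2.48 ± 0.22. By contrast 0 of 18 T and NK cell markers rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.533 with an estimated correlation), among them Cd4 (−2.20 ± 0.53). The T and NK cell list had a mean log2 CPM of 0.08 in SD sample 5 against −0.85 and −1.18 in the other SD samples, and its call on the diet was lost without SD sample 5 (camera adjusted p = 0.247) or MASLD sample 5 (0.0888). The median log2 fold change was −0.75 for T and NK cell and 1.72 for lipid-associated macrophage markers. For NRF2, the oxidative stress regulator, 15 of 28 targets rose and 3 fell (18 and 3 adjusted over the list alone; camera adjusted p = 4.4e-04, adjusted p = 0.317 with an estimated correlation), among the risers Abcc4 (3.06 ± 0.21) and Srxn1 (1.78 ± 0.14). For p53 12 of 28 targets rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.00368, adjusted p = 0.317 with an estimated correlation), led by Cdkn1a (2.60 ± 0.33).

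Hepatocyte genes fell on the MASLD diet, where 0 of 20 hepatocyte markers rose and 15 fell (0 and 17 adjusted over the list alone; camera adjusted p = 1.1e-09, adjusted p = 0.317 with an estimated correlation). They included Ahsg (−1.43 ± 0.16). In the periportal zone 1 of 22 genes rose and 17 fell (1 and 17 adjusted over the list alone; camera adjusted p = 3.0e-10, adjusted p = 0.317 with an estimated correlation). The urea cycle enzyme Ass1 went from 5823 ± 492 to 1329.8 ± 324 CPM (−2.13 ± 0.16), and Agxt fell by 3.39 ± 0.22. Of 28 drug metabolism genes 3 rose and 13 fell (4 and 13 adjusted over the list alone; camera adjusted p = 8.2e-04, adjusted p = 0.412 with an estimated correlation), with Cyp2c54 among the largest falls (−3.73 ± 0.30). Of 24 bile acid genes 3 rose and 10 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.0235, adjusted p = 0.398 with an estimated correlation), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (−0.09 ± 0.33). Of 27 acute phase genes 3 rose and 12 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.441 with an estimated correlation). Of 24 glucose and insulin genes 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0164, adjusted p = 0.441 with an estimated correlation), among them Igf1 (−1.28 ± 0.16) and Pck1 (−1.36 ± 0.24), both lower. The glucose and insulin list did not pass on the diet without SD sample 4 (camera adjusted p = 0.0548). Interferon-stimulated genes went both ways, as 9 of 48 members rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.728), and Igtp, an interferon-induced GTPase, fell by 1.02 ± 0.18.

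Among the 6 largest falls were genes that male mouse livers express at higher levels. Serpina1e (ENSMUSG00000072849, chromosome 12, 103946931 to 103958975), an alpha-1 antitrypsin gene, went from 8676 ± 7418 to 78.6 ± 15.1 CPM (−6.79 ± 0.84, adjusted p = 4.1e-05). Hsd3b5, a steroid dehydrogenase (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), fell by 5.49 ± 0.70, and so did Mup7, a major urinary protein (−5.36 ± 0.84). These 3 genes have near-identical paralogs, with which their reads may be shared. Adgrf1 fell by 5.46 ± 0.79. Obp2a had 323 counts in SD and 3 in MASLD, a ratio of 127 (43.2 to 621). Selenbp2 fell by 5.29 ± 1.22, and Selenbp2 did not pass without SD sample 3 (adjusted p = 0.0655). Of 24 male-biased genes 0 rose and 13 fell (1 and 14 adjusted over the list alone; camera adjusted p = 4.8e-05, adjusted p = 0.468 with an estimated correlation). Their mean log2 CPM was 8.59 in SD sample 3 against 6.91 and 6.99 in the other SD samples and 5.92 to 6.21 in MASLD, so much of the size of this fall rested on SD sample 3. Without it the male-biased list still passed on the diet (camera adjusted p = 0.00479). Of 86 genes listed as ribosomal proteins 3 rose and 66 fell (5 and 68 adjusted over the list alone; camera adjusted p = 7.9e-15, adjusted p = 0.398 with an estimated correlation), with a median of −0.58. With the GC and length trend removed 3 rose and 42 fell, with a median of −0.32. The risers as deposited included the kinase genes Rps6ka1 and Rps6ka4, which are not ribosomal proteins. No library held a count of Xist, the RNA that silences an X chromosome in females.

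In all, 4085 of 13866 genes passed between MASLD and SD, 2164 higher and 1921 lower, and 1437 of them changed at least 2-fold. With the GC and length trend removed 4082 passed, 3300 of them in both. With RLE factors 2055 were higher and 2084 lower, so which direction held more genes depended on scaling. Without MASLD sample 4 the count was 2654.

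**Figure D2:**
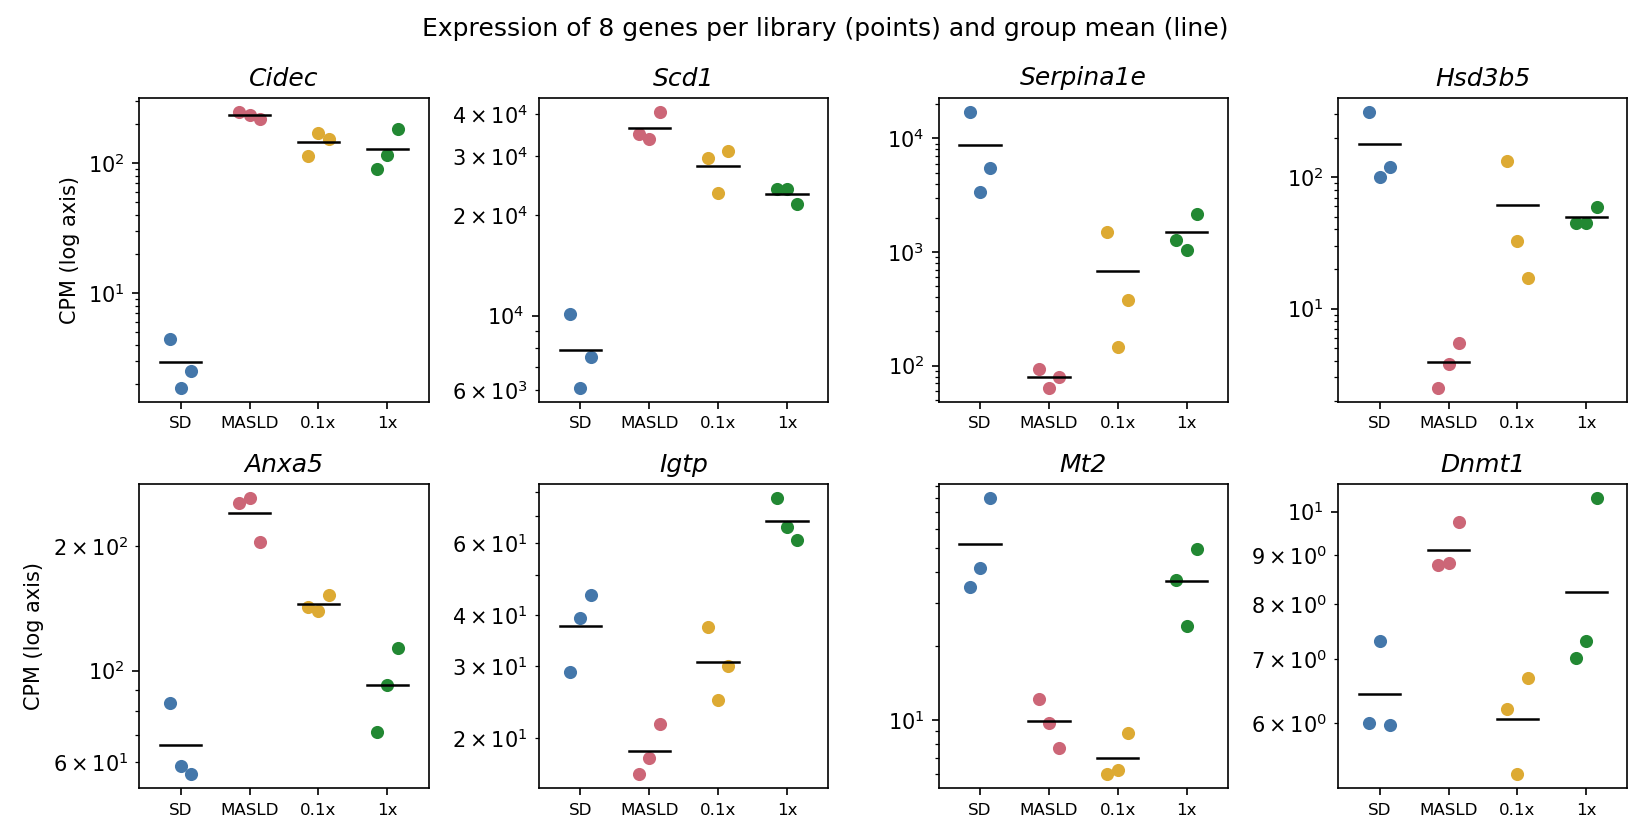
CPM on a log axis for Cidec, Scd1, Serpina1e, Hsd3b5, Anxa5, Igtp, Mt2 and Dnmt1 in the 4 groups, 1 point per library, with a line at each group's mean. Cidec and Scd1 stand higher in MASLD than in SD, Serpina1e and Hsd3b5 lower, and the means of Igtp and Mt2 are highest at 1x among the 3 groups on the MASLD diet.

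At 0.1x Aza-TdC, male-biased genes that had fallen on the diet rose against MASLD. Hsd3b5 rose by 3.95 ± 0.66 (adjusted p = 0.00558), to 61.2 ± 63.2 CPM, Mup7 by 3.92 ± 0.78 and Serpina1e by 3.10 ± 0.71, with wide spread between the 3 samples. Of 24 male-biased genes 10 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 3.2e-07, adjusted p = 0.904 with an estimated correlation), and with the GC and length trend removed 4 rose. Their mean log2 CPM was 7.93 in 0.1x sample 1 against 6.85 and 6.78 in the other 0.1x samples and 5.92 to 6.21 in MASLD, so much of the size of this rise rested on 0.1x sample 1. Without it the male-biased list still passed at 0.1x (camera adjusted p = 3.4e-04). Lcn2, an iron-binding acute phase protein, fell from 33.6 ± 8.95 to 7.64 ± 1.66 CPM (−2.14 ± 0.43), beside 7.63 ± 5.76 in SD. The hepatic transcription factor Onecut1 (−2.43 ± 0.41), the fatty acid elongase Elovl7 (−4.15 ± 0.81), Lrrc8b (−2.35 ± 0.46) and the cytochrome Cyp2b10 (−2.61 ± 0.63) fell most among the named genes that passed with the trend removed too. Ppara, the receptor gene itself, fell by 1.03 ± 0.21. Steap4 (−1.11 ± 0.16), the cell cycle inhibitor Cdkn1a (−1.50 ± 0.31) and the cholangiocyte gene Pkhd1 (−1.23 ± 0.23) also fell. Serpina1e did not pass without 0.1x sample 1 or MASLD sample 3, 4 or 5 (adjusted p from 0.0519 to 0.0673), and Cyp2b10 did not pass without 0.1x sample 1 or MASLD sample 5 (adjusted p from 0.0529 to 0.0838).

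Matrix and cell type markers moved at 0.1x in few genes. Of 39 fibrosis and matrix genes 0 rose and 4 fell (0 and 3 adjusted over the list alone; camera adjusted p = 1.4e-05, adjusted p = 0.904 with an estimated correlation), among them Ccn2 (−0.83 ± 0.18), and with the trend removed 1 fell. The list's mean log2 CPM overlapped between the groups. It was 1.93, 1.64 and 2.69 in 0.1x samples 1, 3 and 4, against 2.62, 3.30 and 2.44 in MASLD samples 3, 4 and 5. Of 21 stellate cell markers 0 rose and 3 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.00863, adjusted p = 0.904 with an estimated correlation), and 0 fell with the trend removed. Of 16 cholangiocyte markers 0 rose and 2 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.00863, adjusted p = 0.904 with an estimated correlation). At 0.1x the cholangiocyte list did not pass without MASLD sample 4 (camera adjusted p = 0.134) or 0.1x sample 3 (0.111), and the stellate list did not without MASLD sample 4 (0.0584). Of 19 lipid-associated macrophage markers 0 rose and 2 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.131), one of them Anxa5 (−0.73 ± 0.17). Of 20 hepatocyte markers 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.121). At 0.1x the lipid-associated macrophage list passed only without MASLD sample 5 (camera adjusted p = 0.00143), and the hepatocyte list only without MASLD sample 5 (0.00582) or 0.1x sample 3 (0.00498). Of 48 interferon-stimulated genes 8 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 0.00239, adjusted p = 0.904 with an estimated correlation), and 3 rose with the trend removed. Ces2a, a carboxylesterase, rose by 0.80 ± 0.15, and Tm7sf2 by 0.52 ± 0.12. Of the lipid genes, Cidec (−0.69 ± 0.25, adjusted p = 0.0810), Scd1 (−0.38 ± 0.19), Cd36 (−0.49 ± 0.23) and Fasn (−0.45 ± 0.34) did not pass. With the trend removed Fasn turned to 0.09, Scd1 stood at −0.18, Cidec at −0.82 and Cd36 at −0.60, and none passed. Ccn2 did not pass without MASLD sample 4 or 5 (adjusted p from 0.0514 to 0.0555), and Anxa5 and Tm7sf2 did not pass without MASLD sample 3 or 4 (adjusted p from 0.0628 to 0.0818).

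Many calls at 0.1x moved with the GC and length trend. As deposited 46 of 86 genes listed as ribosomal proteins rose and 2 fell (66 and 4 adjusted over the list alone; camera adjusted p = 1.8e-20, adjusted p = 0.904 with an estimated correlation), and 6 rose with the trend removed. Of 485 tested pseudogenes 72 rose as deposited and 5 with the trend removed. Mitochondrially encoded genes (camera adjusted p = 0.0109, adjusted p = 0.904 with an estimated correlation) had a median of 0.44 as deposited and −0.10 with the trend removed. At 0.1x the mitochondrially encoded list did not pass without 0.1x sample 1 (camera adjusted p = 0.233) or MASLD sample 5 (0.0620). Mup3 rose by 1.18 ± 0.21 as deposited, and with the trend removed its value was 0.64 (adjusted p = 0.0994). Fabp1, a fatty acid-binding protein, rose by 0.73 ± 0.19 as deposited and stood at 0.14 with the trend removed (adjusted p = 0.592). The iron hormone gene Hamp rose by 1.21 ± 0.30 and stood at 0.66 (adjusted p = 0.245). Fabp1 did not pass without 0.1x sample 3 or MASLD sample 3, 4 or 5 (adjusted p from 0.0606 to 0.0827), and Hamp did not pass without MASLD sample 3 or 4 (adjusted p from 0.0683 to 0.0728).

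At 0.1x, 1826 genes passed, 843 higher and 983 lower. With the trend removed 476 passed, 273 higher and 203 lower, with 342 in both, and the higher share went from 46.2% to 57.4%. It also turned with RLE factors (959 higher and 936 lower, 50.6%) and upper-quartile factors (1024 and 875, 53.9%), so no majority direction is claimed. The genes described for 0.1x were taken largely from those kept: of 81 genes named by rule that passed, 60 did not pass with the trend removed and 63 without at least 1 library. Leaving out 1 library gave 594 (MASLD sample 3), 382 (MASLD sample 4), 461 (MASLD sample 5) and 1145 genes (0.1x sample 1).

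At 1x Aza-TdC, interferon-inducible genes rose against MASLD. Igtp (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591) went from 18.6 ± 2.71 to 68.1 ± 8.40 CPM (1.87 ± 0.18, adjusted p = 1.6e-04), beside 37.7 ± 7.99 in SD. Its relative Irgm2 rose by 1.36 ± 0.15 and Apol9b, which shares reads with a near copy, by 2.05 ± 0.19. Of 48 interferon-stimulated genes 12 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 8.7e-13, adjusted p = 0.359 with an estimated correlation), and 15 rose with the trend removed. Antigen presentation moved both ways, as 9 of 21 genes rose and 2 fell (10 and 6 adjusted over the list alone; camera adjusted p = 1.1e-04, adjusted p = 0.535 with an estimated correlation). The class I gene H2-Q7 rose by 1.08 ± 0.13 and the immunoproteasome gene Psmb8 by 0.91 ± 0.11, while the class II genes H2-Aa (−1.61 ± 0.38) and H2-Ab1 (−1.51 ± 0.37) fell. The list's median was 0.35. Gvin1, another interferon-inducible GTPase, rose by 2.04 ± 0.51. H2-Aa and H2-Ab1 did not pass without 1x sample 2 or 4 or MASLD sample 3 or 4 (adjusted p from 0.117 to 0.208), and Gvin1 did not pass without 1x sample 2, 4 or 5 or MASLD sample 3, 4 or 5 (adjusted p from 0.0555 to 0.221).

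Macrophage, matrix and stress genes fell at 1x. Anxa5 went from 241 ± 30.8 to 92.4 ± 21.2 CPM (−1.38 ± 0.18, adjusted p = 9.8e-04), and Ly6d fell by 2.95 ± 0.51. Of 19 lipid-associated macrophage markers 0 rose and 3 fell (0 and 10 adjusted over the list alone; camera adjusted p = 1.9e-08, adjusted p = 0.359 with an estimated correlation). Of 18 monocyte markers 0 rose and 6 fell (0 and 11 adjusted over the list alone; camera adjusted p = 8.8e-09, adjusted p = 0.359 with an estimated correlation), and 1 of 18 Kupffer cell markers rose and 2 fell (1 and 10 adjusted over the list alone; camera adjusted p = 1.5e-04, adjusted p = 0.486 with an estimated correlation). Of 39 fibrosis and matrix genes 0 rose and 4 fell (0 and 9 adjusted over the list alone; camera adjusted p = 1.1e-09, adjusted p = 0.450 with an estimated correlation), among them Mmp12 (−2.65 ± 0.50). Of 32 cell cycle genes 0 rose and 0 fell (0 and 4 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.413 with an estimated correlation). Of 21 stellate cell markers 0 rose and 2 fell (0 and 7 adjusted over the list alone; camera adjusted p = 8.4e-06, adjusted p = 0.359 with an estimated correlation), and 3 of 20 hepatocyte markers rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.00481, adjusted p = 0.580 with an estimated correlation). At 1x the hepatocyte list did not pass without MASLD sample 4 (camera adjusted p = 0.0704). Of 16 cholangiocyte markers 0 rose and 3 fell (0 and 8 adjusted over the list alone; camera adjusted p = 8.4e-06, adjusted p = 0.444 with an estimated correlation), and 4 fell with the trend removed. At 1x the cholangiocyte list still passed without MASLD sample 4 (camera adjusted p = 4.3e-04). Trem2, Gpnmb, Col1a1 and Timp1 did not pass (Timp1 −2.28 ± 0.62, adjusted p = 0.0617), and of these Timp1 passed with the trend removed (−2.34, adjusted p = 0.0470). Mmp12 did not pass without 1x sample 2 or 4 or MASLD sample 4 (adjusted p from 0.0503 to 0.0864).

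Stress response genes fell with them. Of 28 NRF2 targets 0 rose and 6 fell (0 and 9 adjusted over the list alone; camera adjusted p = 2.3e-07, adjusted p = 0.178 with an estimated correlation), led by the glutathione transferases Gstm3 (−1.99 ± 0.21, adjusted p = 2.1e-04) and Gstm2 (−0.94 ± 0.14). Of 24 unfolded protein response genes 0 rose and 6 fell (0 and 9 adjusted over the list alone; camera adjusted p = 2.3e-06, adjusted p = 0.178 with an estimated correlation), among them Manf (−0.99 ± 0.15) and Creld2 (−1.07 ± 0.18), which reside in the endoplasmic reticulum. Manf went from 86.2 ± 9.96 to 43.3 ± 5.66 CPM, beside 81.7 ± 10.8 in SD.

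Metabolic genes changed at 1x in smaller numbers. Plin2, the main lipid droplet coat protein of hepatocytes, went from 1146 ± 49.9 to 647 ± 82.0 CPM (−0.82 ± 0.13, adjusted p = 0.00473), and Mogat1 fell by 1.02 ± 0.20. Of 25 lipid droplet and uptake genes 0 rose and 3 fell (0 and 6 adjusted over the list alone; camera adjusted p = 5.0e-04, adjusted p = 0.461 with an estimated correlation). At 1x the lipid droplet list did not pass without 1x sample 2 (camera adjusted p = 0.0836). Cidec (−0.87 ± 0.25, adjusted p = 0.0828), Scd1 (−0.66 ± 0.19, adjusted p = 0.0761), Cd36 (−0.63 ± 0.23) and Fasn (−0.13 ± 0.34) did not pass. Fgf1, a growth factor, rose by 0.90 ± 0.14, and Ppp1r3b, a glycogen-targeting phosphatase subunit, by 1.00 ± 0.15. Of 24 glucose and insulin genes 3 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00404, adjusted p = 0.481 with an estimated correlation). Mt2, a metal-binding metallothionein (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568), rose by 1.90 ± 0.31. Cyp7a1 rose by 1.32 ± 0.33 (adjusted p = 0.0476). Of 24 male-biased genes 4 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.600 with an estimated correlation), among them Serpina1e (4.25 ± 0.75) and Hsd3b5 (3.65 ± 0.65). Mogat1 did not pass without 1x sample 2 or MASLD sample 3 (adjusted p from 0.0659 to 0.0877), Cyp7a1 did not pass without 1x sample 2 or 4 or MASLD sample 3, 4 or 5 (adjusted p from 0.0659 to 0.206), Serpina1e did not pass without MASLD sample 4 (adjusted p = 0.0594), and Hsd3b5 did not pass without MASLD sample 3 or 4 (adjusted p from 0.0554 to 0.0600).

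At 1x, 431 genes passed, 207 higher and 224 lower, and with the trend removed 626 passed, 419 of them in both. Leaving out 1 library gave 102 (MASLD sample 3), 83 (MASLD sample 4), 148 (1x sample 2), 154 (1x sample 4) and 216 genes (1x sample 5), and DESeq2 called 825.

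Between the doses, metallothionein and glucose genes were higher at 1x than at 0.1x, and clock genes moved both ways. Mt2 stood at 7.03 ± 1.55 CPM at 0.1x and 36.9 ± 12.7 at 1x (2.39 ± 0.32, adjusted p = 0.00178), against 52.1 ± 24.5 in SD and 9.85 ± 2.28 in MASLD. Mt1 was higher by 1.95 ± 0.32, Igfbp1, which binds insulin-like growth factors, by 1.68 ± 0.22, Ppp1r3b by 1.38 ± 0.15 and Ddit4, a brake on mTOR, by 1.75 ± 0.22. Of 24 glucose and insulin genes 6 were higher and 0 lower (6 and 1 adjusted over the list alone; camera adjusted p = 6.9e-04, adjusted p = 0.730 with an estimated correlation). Of 21 clock and output genes 7 were higher and 2 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.00166, adjusted p = 0.730 with an estimated correlation), with Lonrf3 (2.43 ± 0.35) and Per1 (0.84 ± 0.13) higher and Dbp (−0.76 ± 0.12) and Bhlhe41 (−1.76 ± 0.39) lower, and 3 were higher and 2 lower with the trend removed. Of 48 interferon-stimulated genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.843 with an estimated correlation), among them Gbp7 (1.62 ± 0.24). Between the doses the interferon-stimulated list did not pass without 1x sample 2 (camera adjusted p = 0.0770). Ppara was higher by 1.06 ± 0.21. Ppara and Bhlhe41 did not pass without 1x sample 2 (adjusted p from 0.0578 to 0.0816).

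Macrophage and stress genes were lower at 1x than at 0.1x. The chemokine gene Cxcl13 differed by −3.07 ± 0.55 and the myeloid receptor gene Clec4a2 by −1.80 ± 0.39. Of 18 Kupffer cell markers 0 were higher and 7 lower (0 and 11 adjusted over the list alone; camera adjusted p = 9.9e-05, adjusted p = 0.730 with an estimated correlation), and 3 were lower with the trend removed. Of 18 monocyte markers 0 were higher and 6 lower (0 and 9 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.730 with an estimated correlation), and 1 was lower with the trend removed. Of 28 NRF2 targets 0 were higher and 8 lower (1 and 13 adjusted over the list alone; camera adjusted p = 5.6e-05, adjusted p = 0.603 with an estimated correlation), and 6 were lower with the trend removed. Clec12a (−1.19 ± 0.20), Manf (−1.12 ± 0.15) and the stress gene Gadd45a (−1.43 ± 0.24) were lower. Of 86 genes listed as ribosomal proteins 1 were higher and 33 lower (3 and 52 adjusted over the list alone; camera adjusted p = 3.8e-15, adjusted p = 0.730 with an estimated correlation), and 5 were lower with the trend removed. Of 485 pseudogenes 96 were lower as deposited and 15 with the trend removed. Mitochondrially encoded genes (camera adjusted p = 0.00359, adjusted p = 0.843 with an estimated correlation) had a median of −0.47 as deposited and 0.04 with the trend removed. Between the doses the mitochondrially encoded list did not pass without 0.1x sample 1 (camera adjusted p = 0.0947) or 1x sample 2 (0.180).

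Klb was higher at 1x than at 0.1x by 0.47 ± 0.15 (adjusted p = 0.0474), and by 0.40 with the trend removed (adjusted p = 0.102). Klb did not pass without 0.1x sample 1, 3 or 4 or 1x sample 2 or 4 (adjusted p from 0.0642 to 0.222). Fgf21 (−0.16 ± 0.26), Scd1 (−0.28 ± 0.19) and Cidec (−0.17 ± 0.25) did not pass between the doses.

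Between the doses 1802 genes passed, 989 higher and 813 lower, a higher share of 54.9%. With the trend removed 655 passed, 291 higher and 364 lower (44.4%), 491 of them in both, and with upper-quartile factors 803 were higher and 1054 lower (43.2%). Leaving out 1 library gave 1135 (0.1x sample 1), 210 (1x sample 2) and 782 genes (1x sample 5), and a fit of these groups alone gave 744.

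**Figure D3:**
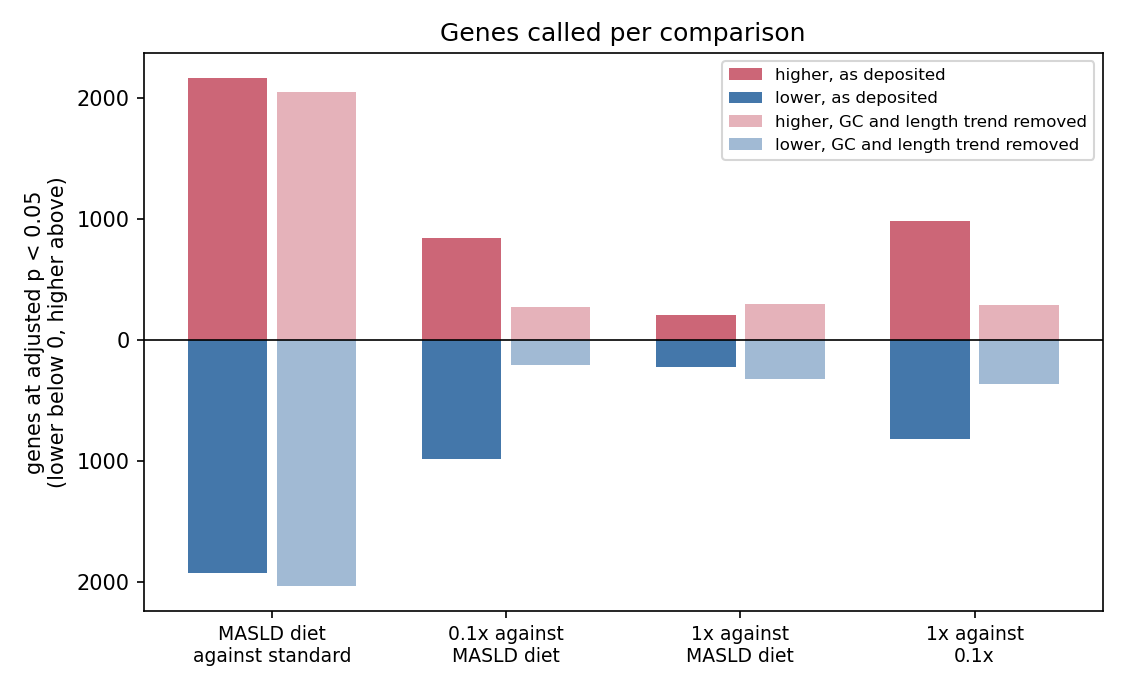
Number of genes that passed, higher and lower, in the 4 main comparisons, as deposited and with the GC and length trend removed. The bars at 0.1x go from 843 and 983 to 273 and 203, and those of the diet from 2164 and 1921 to 2055 and 2027.

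Genes changed by the diet were then followed at each dose. Of 2164 genes higher on the MASLD diet, 440 (20.3%) fell at 0.1x and 168 (7.76%) at 1x, and of 1921 lower ones 508 (26.4%) rose at 0.1x and 139 (7.24%) at 1x. Anxa5 fell at both doses, and Serpina1e and Hsd3b5 rose at both. In the diet's own direction 16 diet genes moved at 0.1x and 5 at 1x. Both comparisons used the same MASLD libraries, so opposite signs arise by chance as well. Simulated unchanged groups gave 0 genes, but at most 2 genes passed in any such comparison, so this count is no measure of chance overlap between lists of these sizes. Independent lists of these sizes would share 153 (higher, then lower) and 117 (lower, then higher) genes at 0.1x, and 35.0 and 28.7 at 1x. The correlation of fold changes across genes was −0.512 at 0.1x (simulated −0.490) and −0.558 at 1x (simulated −0.500). The covariance was −0.153 at 0.1x (simulated −0.0238, a difference of −0.129) and −0.146 at 1x (simulated −0.0240, a difference of −0.122). The MASLD libraries are too few to split, so part of these overlaps may come from sharing them. With the trend removed 300 genes moved back at 0.1x and 436 at 1x. Leaving out 1 library gave 629 (SD sample 5), 296, 179 and 282 (MASLD samples 3, 4 and 5) and 607 genes (0.1x sample 1) at 0.1x. At 1x it gave 79 and 58 (MASLD samples 3 and 4) and 112, 109 and 163 (1x samples 2, 4 and 5).

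The doses shared 137 genes called in the same direction, 65 higher and 72 lower, among them Hsd3b5 and Anxa5. Independent lists would share 12.6 and 15.9, and simulated unchanged groups 0.05, which is no measure of chance overlap for the same reason, and part of the excess may come from the shared MASLD libraries. The correlation of fold changes across genes was 0.455 (simulated 0.502), and the covariance 0.0694 (simulated 0.0241, a difference of 0.0452). Leaving out 1 library gave 28, 13 and 85 shared genes (MASLD samples 3, 4 and 5), 90 (0.1x sample 1) and 76, 57 and 76 (1x samples 2, 4 and 5).

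The mean of both doses against MASLD gave 571 genes, 226 higher and 345 lower. Of 39 fibrosis and matrix genes 0 rose and 7 fell (0 and 13 adjusted over the list alone; camera adjusted p = 1.4e-09, adjusted p = 0.556 with an estimated correlation), and 12 of 48 interferon-stimulated genes rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 2.8e-09, adjusted p = 0.556 with an estimated correlation). The count was 59, 24 and 293 without MASLD samples 3, 4 and 5, and 225 and 348 without 1x samples 4 and 5. Across the diet genes, the diet's fold change and the difference between the doses had a Spearman correlation of −0.0135 (Pearson −0.0970) over 4085 genes, which are not independent replicates. It was −0.225 with the trend removed and positive without SD sample 4 (0.0569), 0.1x sample 4 (0.0460) or 1x sample 4 (0.0551), so its sign was not settled. Genes lower on the diet were lower at 1x than at 0.1x as a set (camera p = 0.000455, p = 0.199 with an estimated correlation), which runs against a negative correlation, and genes higher on it did not pass (camera p = 0.440). Both set tests were run as deposited only, and whether they hold with the trend removed was not tested.

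Both treated groups still differed from SD. Cidec stood above SD at 145 ± 28.3 CPM at 0.1x (5.63 ± 0.32) and 129 ± 47.6 at 1x (5.45 ± 0.32). At 0.1x 18 of 34 PPARA targets rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 5.2e-12, adjusted p = 0.253 with an estimated correlation), and at 1x 22 of 34 rose and 0 fell (24 and 1 adjusted over the list alone; camera adjusted p = 2.4e-14, adjusted p = 0.360 with an estimated correlation). At 0.1x 1 of 22 periportal genes rose and 18 fell (1 and 18 adjusted over the list alone; camera adjusted p = 1.7e-10, adjusted p = 0.253 with an estimated correlation), and at 1x 1 of 22 rose and 18 fell (1 and 18 adjusted over the list alone; camera adjusted p = 3.4e-10, adjusted p = 0.360 with an estimated correlation). At 0.1x 4 of 39 fibrosis and matrix genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 6.6e-04, adjusted p = 0.545 with an estimated correlation), and at 1x 5 of 39 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.649 with an estimated correlation). At 0.1x 8 of 19 lipid-associated macrophage markers rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2.3e-05, adjusted p = 0.323 with an estimated correlation), and at 1x 5 of 19 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0315, adjusted p = 0.618 with an estimated correlation). At 0.1x 2872 genes passed against SD, 1366 higher and 1506 lower, and at 1x 2739, 1374 higher and 1365 lower. Over all 4 groups 5323 genes passed a joint test. Without SD sample 4 the count at 0.1x was 1790, and at 1x it was 1726 without SD sample 5 and 1699 without 1x sample 2.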

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

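The tests of clock phase, of glucocorticoid-responsive genes, of the libraries with the strongest trend and of the share of ribosomal protein genes and pseudogenes were chosen only after the result was seen, and the removal of the GC and length trend after the counts of calls were seen but before its own result. The difference between the doses was tested directly, and 1802 genes passed. Among lists, fry found a difference between the doses for glucose and insulin genes (adjusted p = 0.0304), NRF2 targets (adjusted p = 0.0202) and clock and output genes (adjusted p = 0.0283). Arpp19 (ENSMUSG00000007656), a regulator of mitotic phosphatase activity, rose at 0.1x (0.46 ± 0.13) and fell at 1x (−0.60 ± 0.13) against MASLD, a difference of −1.07 ± 0.13 (adjusted p = 0.00150). Abtb2 (ENSMUSG00000032724) fell at 0.1x (−0.53 ± 0.16) and rose at 1x (0.78 ± 0.16), a difference of 1.31 ± 0.16 (adjusted p = 0.00150). These were the 2 genes called in opposite directions at the doses, and they were named after their values were seen. Klb, fixed in advance, differed by 0.47 (adjusted p = 0.0474), a call not kept with the trend removed (0.40, adjusted p = 0.102).

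More genes passed at 0.1x (1826) than at 1x (431), although 0.1x is the lower dose. A single 0.1x library as the source is argued against by 1145 calls, the lowest count without 1 of those libraries, and so are ribosomal protein genes, mitochondrially encoded genes and pseudogenes, which made up 7.17% of the calls at 0.1x alone (121 of 1687). With the GC and length trend removed 476 genes passed at 0.1x and 626 at 1x, so the larger count at 0.1x may come from a trend that differs between libraries. The strongest trends alone do not account for it, since 1595 and 353 genes passed without 0.1x sample 3 and 1x sample 2. Other libraries carry the trend too (20.6% in MASLD sample 5, 17.3% in 0.1x sample 4), and whether they account for the larger count was not tested. A MASLD library, sample 5, stays open as a source, since the counts at 0.1x and 1x were 461 and 396 without it. Without MASLD sample 3 (594 and 102) or 4 (382 and 83) the count at 0.1x stayed well above that at 1x. The gap also depended on the threshold, since with all libraries 116 and 91 genes passed at an adjusted p under 0.01. The correction also takes out any effect of the drug that follows GC content or length, so such an effect stays open too, as does a biological difference in the 342 genes called both ways, which was not tested further.

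Clock genes, in both directions, and metallothioneins differed between the doses. If time of day at collection differed, genes that peak in the evening and in the morning should move apart. Their medians were 0.30 (10 genes) and 0.63 (4 genes), a difference of −0.33, which decides nothing with so few genes. The evening genes that passed also moved apart among themselves. Per1 (0.84), Per2 (0.89) and Per3 (0.96) were higher, and Dbp (−0.76) and Bhlhe41 (−1.76) lower. A median over them can hide a shift, so a difference in time of day stays open. Genes that respond to glucocorticoids, without the clock gene Per1, had a median of 0.93, with 4 of 9 higher and 0 lower at 1x. The rotation test fry of limma, with 3 libraries per dose, gave an adjusted p = 0.000552 (1 list tested, so equal to its unadjusted value). That list was written after the values were seen and holds genes already called at a dose, such as Cdkn1a, Pdk4 and Tat, so its p may be too small. The test was run only as deposited and with all libraries. A difference in glucocorticoid signal, such as stress or feeding state at collection, stays open. The same genes respond to other signals, and the labels give neither time nor feeding state. An effect of the dose itself also stays open.

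Each comparison of 3 against 3 samples allows 10 splits, too few for a share under 0.05. The real split gave the most genes, and 1 of the 10 splits reached it, in all 6: 4085 for the diet, 1826 at 0.1x, 431 at 1x, 1802 between the doses and 2739 at 1x against SD, each with a highest other split of 0, and 2872 at 0.1x against SD with a highest other of 1. For the joint test 1 of 100 splits, the real one itself, gave as many genes as the real one (5323, highest other 1301). That share lies under 0.05, which argues against chance alone for some difference among the groups. The diet alone could give it, so it says nothing of the doses. For both doses against MASLD in 2 groups, 3 of 84 splits gave as many as the real 100, and the highest other split gave 2022. Splits that mixed the groups gave 0 or 1 gene, so only splits along group lines could score. The test thus shows that the groups stood apart, and it cannot exclude chance for an effect common to both doses. The split with 2022 genes sets the 0.1x libraries apart from the rest, and the third split sets the 1x libraries apart (198 genes). As deposited each dose thus stood apart in more genes than MASLD did, but each of these splits pools 2 unlike groups. With the doses kept as separate groups their mean against MASLD gave 571 genes. The splits were not run with the GC and length trend removed, so no order of the groups is claimed.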

How the results depend on the processing

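The removal of the GC and length trend, the block by library-name numbers and the runs without doubted libraries were chosen after seeing the data. The comparison of diets kept its side of 1.5-fold under all settings run except an adjusted p under 0.01 (2254 genes), a 2-fold minimum (1437) and leaving out MASLD sample 4 (2654). RLE and upper-quartile factors moved no count of calls by over 1.5 times. The cause was not tested for the changes below, except that a stricter threshold lowers a count by construction. A block in effect also leaves out samples whose number no other group has.

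DESeq2 gave 825 genes at 1x, 1239 for the mean of both doses, 568 diet genes moved back at 1x and 269 calls shared by the doses. With no low-count filter these were 1131, 1413, 781 and 411. At a mean of at least 1 CPM the correlation of the diet effect with the dose effect was 0.0322. Fits of only the groups compared gave 1013 genes at 1x, 744 between the doses and 1660 at 0.1x against SD. At an adjusted p under 0.01 counts were 116 at 0.1x, 91 at 1x, 254 between the doses, 1320 and 1357 against SD at 0.1x and 1x, 73 for the mean of both doses, 2624 over all groups, 60 and 69 moved back and 10 shared. With a 2-fold minimum they were 284, 186, 330, 977, 800, 132, 1905, 122, 122 and 40 in that order, and the correlation was −0.163. With the trend removed 476 genes passed at 0.1x, 655 between the doses and 300 moved back at 0.1x, and the correlation was −0.225. Without the doubted libraries, 0.1x sample 3 and 1x sample 2, 260 genes passed between the doses and 975 for the mean of both doses.

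Replicate numbers recur across groups, and 12 pairs of samples share one. None had a correlation of deviations over 0.1 (−0.215 to 0.0757), and 2 pairs correlated best with each other, so the numbers were not taken to pair samples. With a replicate block 33 genes passed at 0.1x, 53 at 1x, 1379 and 1122 against SD, 130 for the mean of both doses, 2538 over all groups, 18 and 43 moved back and 4 shared. Number 1 occurs only at 0.1x and number 2 only at 1x. The block therefore in effect leaves out 0.1x sample 1 and 1x sample 2 and uses up degrees of freedom, so these lower counts do not measure an effect of pairing. Between the doses edgeR with the block called 0 genes, with 1639 at an unadjusted p under 0.05, and DESeq2 with the block called 78. In the library names 8 also occurs only at 1x, so a block by those numbers leaves 1x sample 4 alone to carry 1x. With a block by library-name numbers the counts were 110, 26, 1160, 249, 55, 2008, 70, 21 and 13 in the same order and 1 between the doses, and the correlation was −0.220. In list tests with the replicate block, mitochondrially encoded genes turned direction at 1x (adjusted p = 0.00180) and between the doses (0.365), and male-biased genes between the doses (0.0161).

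Leaving out each library in turn gave 2654 to 3850 genes for the diet, 382 to 1599 at 0.1x, 83 to 396 at 1x, 210 to 1844 between the doses, 1790 to 2619 and 1699 to 2559 against SD, 24 to 738 for the mean of both doses and 4048 to 5572 over all groups. Diet genes moved back numbered 179 to 938 at 0.1x and 58 to 381 at 1x, shared calls 13 to 145, and the correlation ran from −0.119 to 0.0569. It turned positive without SD sample 4 (0.0569), 0.1x sample 4 (0.0460) and 1x sample 4 (0.0551). Without 1x sample 2 mitochondrially encoded genes turned direction at 1x (adjusted p = 0.0253), in a range of 0.0242 to 0.922 over the libraries left out. The diet log2 fold changes of Pnlip and Ctrb1 were 0 without MASLD sample 4 and at most 8.28 and 7.42 without another library. Ptprb turned to 0.0760 at 0.1x and −0.0137 between the doses with the trend removed.

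Of the named genes that passed, calls lost without at least 1 library numbered 21 of 130 for the diet, 63 of 81 at 0.1x, 50 of 65 at 1x and 46 of 74 between the doses. With the trend removed 5, 60, 3 and 39 were lost, with the replicate block 8, 79, 49 and 74, with fits of only the groups compared 0, 10, 1 and 20, and under DESeq2 4, 4, 2 and 1. In list tests fry kept 117 of 156 results on their side of the threshold, but these include lists that camera had not called. Camera at the preset correlation made 66 calls over the main comparisons. All 66 were lost with an estimated correlation, and fry lost 38 of them. In the simulated data at these depths, with 200 changed genes, 1.5-fold changes were recovered in 18.0% of genes for the diet and 24.6% at 0.1x. Far more genes passed in the real data (4085 and 1826), which makes the adjusted threshold less strict, so these shares do not carry over to it. Of those calls 1437 and 284 changed at least 2-fold, so most were smaller changes. A fit of only the groups compared gives no value for the joint test, and genes under a mean of 1 CPM have none under that filter.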

Other observations

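All tests of male-biased genes in this part were chosen only after the result was seen. The hepatocyte tests after the one on the whole list were added once that one had not counted against the explanation, and those of the rise and of the largest falls had their bounds set with values in view. Blood and adipose genes changed in the diet-fed livers. Of 10 erythroid genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.429), with Bpgm up by 0.79 ± 0.17 and Klf1, a red cell transcription factor, down (−1.87 ± 0.28). At 1x Klf1 rose by 1.34 ± 0.28 and the globin gene Hbb-bs fell by 1.17 ± 0.28. Klf1 did not pass without 1x sample 4 or 5 or MASLD sample 3 or 4 (adjusted p from 0.0568 to 0.125), and Hbb-bs did not pass without 1x sample 2 or 5 or MASLD sample 3 or 4 (adjusted p from 0.0706 to 0.192). Of 7 adipocyte genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.160), with Fabp4 (1.55 ± 0.16) and Pparg (1.29 ± 0.16) higher and Car3 lower (−1.64 ± 0.24). At 1x Fabp4 (−0.81 ± 0.16) and Pparg (−0.65 ± 0.16) fell against MASLD. Fabp4 and Pparg did not pass without 1x sample 2 or 4 or MASLD sample 3 or 4 (adjusted p from 0.0540 to 0.182). Imprinted genes rose on the diet in Peg3 (2.62 ± 0.30) and Impact (1.56 ± 0.18), where 5 of 19 members rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0647), and at 1x 0 of 19 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.277).

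Immediate early genes and markers of immune cells other than macrophages also changed on the diet. Of 10 B and plasma cell genes 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.112), and the fall of Igkc (−3.83 ± 0.95) and Jchain (−3.64 ± 0.92) rested on SD sample 5: Igkc and Jchain did not pass without SD sample 5 (adjusted p from 0.177 to 0.186). Of 18 immediate early genes 3 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.219), with Ier2 (−1.50 ± 0.13) and Junb (−1.72 ± 0.20) lower and Klf6 higher (1.79 ± 0.25). Of 19 female-biased genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.119), with Abcd2 up by 1.82 ± 0.28. The female-biased mean log2 CPM was 0.65 in SD sample 3 against 2.10 and 2.13 in the other SD samples and 2.18 to 2.52 in MASLD, the mirror image of the male-biased mean in that sample (8.59 against 6.91 and 6.99). On the diet the female-biased list did not pass without SD sample 3 (camera adjusted p = 0.530) and passed without MASLD sample 4 (0.0432) or SD sample 5 (0.0398). Pancreatic genes were seen at low counts: Pnlip was at least 23.7-fold and Ctrb1 at least 12.96-fold higher in MASLD than in SD, where neither had a count, and all their MASLD counts came from sample 4. Ctrb1 had 70 counts at 0.1x and 2 at 1x, a ratio of 46.7 (12.5 to 393). Between the doses Ctrb1 did not pass without 0.1x sample 1, 3 or 4 or 1x sample 2, 4 or 5 (adjusted p from 0.0654 to 0.190). Of germline genes silenced by DNA methylation 4 were tested, and Hormad2 rose on the diet (3.06 ± 1.01), a call that did not hold in these cases: Hormad2 did not pass without MASLD sample 3 or 5 or SD sample 3 or 5 (adjusted p from 0.0599 to 0.120).

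Male-biased genes fell on the MASLD diet and rose with Aza-TdC. Reads shared within the Mup, Serpina1, Cyp4a12, Ugt2b and Hsd3b families are argued against as the whole source of the fall. The 11 male-biased genes outside such families had a median of −0.82 on the diet, and 6 of them fell. Random lists of this size reach −0.33 at their lower 2.5 percentile. Their medians were 0.51 at 0.1x and 0.44 at 1x. On the diet they lay −0.04 from hepatocyte genes, and 0.28 without SD sample 3. Shared reads stay open for Selenbp2, Gstp1 and Cyp2d9, which are among the 11 and have close relatives too. A lower share of hepatocytes is consistent with the list as a whole, whose median lay −0.15 from that of hepatocyte genes (permuted range −0.39 to 0.40), and stays open as the cause of the largest falls, since 5 male-biased genes, 4 of them in such families, fell further than Agxt (−3.39), which fell most in the general, periportal and pericentral hepatocyte lists, but only 2 did without SD sample 3. A loss of hepatocytes with all other cell types higher alike stays open too. T and NK cell markers lay −2.47 from lipid-associated macrophage markers, outside the range of random splits (−1.25 to 1.38). These 2 lists were picked with their medians of −0.75 and 1.72 in view, so a large difference was likely beforehand and decides nothing. The T and NK cell list also lost its camera call without SD sample 5 (adjusted p = 0.247) or MASLD sample 5 (0.0888). Without 1 library the difference between the 2 lists ran from −2.71 to −2.06, each outside its own range. This range and the others here treat genes as independent, though markers of a cell type move together. They do not measure the spread between libraries, so the weight of these comparisons is uncertain. A higher share as the cause of the rise stays open at both doses, since male-biased genes lay 0.68 above hepatocyte genes at 0.1x (medians 0.93 and 0.25, permuted range −0.31 to 0.27), but those outside the families 0.26 (range −0.35 to 0.22) and, without 0.1x sample 1, 0.29 (range −0.31 to 0.32), and at 1x the medians of 0.50 and 0.23 differed by 0.26 (range −0.23 to 0.24) and outside the families by 0.21 (range −0.28 to 0.26), as do a lower share on the diet through the types that rose and a change in the hormone signals that set sex-biased expression, which was not tested.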
